A study of Mus musculus with 10 samples.

How the data were processed

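RNA was measured in livers of male C57BL/6 NHsd mice, an inbred laboratory strain, on Affymetrix expression arrays of the mouse genome, on which several short probes near the 3' end of a transcript form a probe set. Per the series' design text, the mice received phosphate-buffered saline (PBS) or lipid nanoparticles carrying small interfering RNA (siRNA) through the tail vein at 1.5 mg/kg, and the livers were taken on day 5. The groups, from the sample titles, were PBS (2 arrays), a control siRNA (4 arrays) and siRNAs against all Rab5 genes (4 arrays), 10 arrays in all. The titles call the control a scrambled non-targeting RNA, while the design text names luciferase as its target, so it is called the control siRNA here. The titles number the livers within a group but do not say in words that each came from its own mouse, so p-values measure the spread between these samples. No scan date or batch is given in the sources used here.

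The deposited table holds log2 expression values for 45101 probe sets. Per the submitters' processing notes, which list tools without their order, Affymetrix Expression Console, robust multi-array average (RMA) and Partek 6.6 were used. RMA subtracts background, equalises the distributions of the arrays and summarises the probes on the log2 scale, so a general shift of all transcripts in 1 group would not be seen. The median of the deposited log2 values per array lay between 4.29 and 4.37 and the highest value per array between 14.43 and 14.48. No detection calls were used, so low values have no measured background: changes of dim probe sets are compressed, and the number of arrays limits the precision. No genome build is named in the sources used here, and no coordinates are given.

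Gene names came from the platform annotation supplied with the table. It gave exactly 1 symbol to 34958 probe sets and several to 932, while 9160 were unnamed here, besides 64 control probe sets, which were left out. Of the probe sets with 1 symbol, 34754 had an Entrez identifier in the RefSeq gene table used, that of the mouse assembly GRCm38.p6, and 0 symbols needed updating. The plan was to match list members through older symbols and synonyms too. This was dropped when the matched names were inspected, since several synonyms led to a different gene (Trf to Trh and Loxl2 to Loxl3, for example). List members were therefore matched by exact symbol, with 1 older name (Igj, now Jchain) replaced by hand, which departs from the plan. A gene whose name is absent from the annotation was not analysed here.

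Probe sets were kept if their value lay above the median of the whole table (4.33) in at least 2 arrays, which left 24281. The kept probe set with the highest mean over all arrays stood for its gene, giving 12855 genes. A linear model with a mean per group was fitted to all 10 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that all groups shared 1 estimate of the spread. Genes were called at an adjusted p (Benjamini-Hochberg) under 0.05. An adjusted p of a gene below is that of limma, and standard errors (SE) are the moderated ones of that model. Group values are mean and SD on the log2 scale.

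The 35 gene lists were written before the data were examined and held 738 entries, 666 of them found on the array. They covered the Rab5 GTPases, Rab5 effectors and endosomes, lysosomes, endocytic receptors, glucose, lipid, bile acid and amino acid metabolism, hepatocyte functions, sex-biased and growth hormone genes, drug metabolism, stress responses, cell cycle, inflammation, the circadian clock, and markers of other cell types in or around the liver. Lists with at least 5 measured members were tested with limma's camera, which compares the list with all other genes, at its preset correlation of 0.01 between genes. An adjusted p of a list is that of camera over the 33 lists tested in a comparison unless said otherwise. Camera with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance in 1 direction, were run as alternatives. A list score is the mean log2 value of its members in an array, set to 0 at the mean of the control siRNA arrays.

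Genes named in the text followed a rule from the same plan. It took the 3 Rab5 genes, and the 10 largest rises and 10 largest falls among genes called for Rab5 siRNA against control siRNA with no overlap between the groups, passing over symbols of unnamed transcripts (ending in Rik, or Gm, LOC or BC with digits). It took from each list up to 4 called members with the largest change, or the members with the largest change as values where fewer than 2 were called. It took 21 genes of glucose, lipid, insulin and endosome biology, of which 18 were measured and 3 were not analysed here. For control siRNA against PBS it took called genes, of which there were 0. The rule took 152 genes, and the text prints a part of them. Where a name falls outside the rule, the text says that it was chosen after its values were seen.

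The replicate numbers in the titles recur in each group. Deviations from the group mean over all genes correlated between the control and Rab5 arrays of the same number with r = 0.391, 0.149, 0.186 and 0.312 (across genes, which are not independent replicates). Each was above 0.1, so the numbers were taken to pair the samples, on the evidence of the data and not of the labels. The planned fit had no block, and the fit with the replicate number as a block was an alternative. The largest correlation was not with the same number for control replicate 2 or Rab5 replicate 2.

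The fits and list tests were checked on simulated data with the real design. With 200 of 12855 genes changed by 1 on the log2 scale, 99.5% were called for Rab5 siRNA against control siRNA, 93.5% for control siRNA against PBS and 97% for Rab5 siRNA against PBS. With a change of 0.5 the shares were 44.5%, 0.5% and 0.5%. These shares hold for 200 changed genes, since the adjusted p depends on how many genes change. All 5 simulated shifted lists were called, and 0 of 26 others. Genes were drawn independently in these simulations, so they do not show how often lists of correlated genes are called without a shift.

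Alternatives were no filter or one at the 75th percentile, quantile normalization or median centring of the deposited values, the mean of a gene's probe sets or its most variable one, all kept probe sets as the unit, a variance trend with robust estimation, array weights, only the 2 groups compared, the replicate block, each array left out, an adjusted p under 0.01, and at least a 2-fold change. Chosen after seeing the data were the removal of the arrays numbered 1 in both siRNA groups, the removal of all arrays numbered 2, and a covariate for RNA quality. Exact permutation tests were 2-sided and run in Python 3.11.15 with NumPy 2.4.6.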

Results

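RNA from 10 mouse livers was measured on arrays: 2 livers after PBS, 4 after a control siRNA and 4 after siRNAs against the Rab5 genes, small GTPases of early endosomes. The siRNAs were given in lipid nanoparticles at 1.5 mg/kg and the livers taken on day 5. After filtering, 12855 genes were tested. Values of arrays of the same group correlated with r between 0.975 and 0.992 across genes, and those of different groups with r between 0.942 and 0.991 (genes are not independent replicates). Changes are differences of group means on the log2 scale, Rab5 siRNA minus control siRNA unless said otherwise, with n = 4 arrays in each siRNA group and n = 2 in the PBS group.

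The targeted genes come first. Rab5a fell from 8.67 ± 0.228 (SD, n = 4) with control siRNA to 6.86 ± 0.402 (SD, n = 4) with Rab5 siRNA, a change of -1.81 (SE 0.176, adjusted p = 1.16e-05) that left 28.6% of the signal. Rab5c fell from 9.21 ± 0.155 to 7.21 ± 0.159 (SD, n = 4 each), a change of -1.99 (SE 0.110, adjusted p = 1.64e-07) that left 25.1%. Rab5b lay near the median of the table, at 4.34 ± 0.156 with control siRNA and 4.10 ± 0.246 with Rab5 siRNA. Its difference of -0.24 (SE 0.127, adjusted p = 0.194) did not pass, and at this signal a fall would be compressed. Another Rab5b probe set, too dim for the filter, differed by 0.17 (SE 0.114, adjusted p = 0.418 by limma over all probe sets). In PBS livers the means were 8.74 for Rab5a and 9.29 for Rab5c. The list of the 3 Rab5 GTPases was too short for a list test, and 2 of its members fell (2 adjusted over the list alone).

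**Figure D1:**
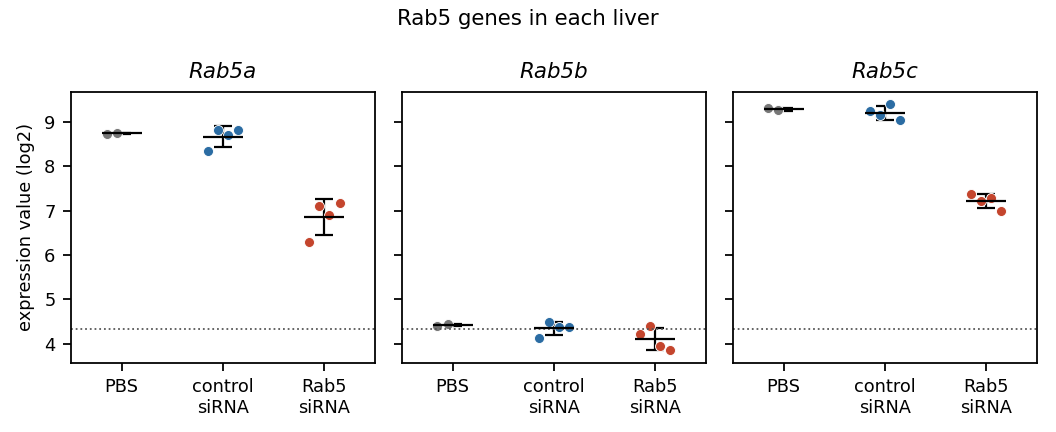
Log2 values of Rab5a, Rab5b and Rab5c (vertical axis) in each array (points) by group, with lines for the group mean and SD and a dotted line at the median of the table, 4.33. The Rab5 siRNA arrays lie below the control siRNA arrays for Rab5a (means 6.86 and 8.67) and Rab5c (7.21 and 9.21), while Rab5b lies near the dotted line in all groups.

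For Rab5 siRNA against the control siRNA, the comparison the design is built on, limma called 2993 of 12855 genes, 1771 up and 1222 down. Of these, 496 changed at least 2-fold, 325 up and 171 down. No other set of siRNAs against the Rab5 genes was among the groups. Effects of silencing Rab5 and other effects of these siRNAs can therefore not be told apart here. The largest rises included Afp, the fetal albumin-like protein (3.51, SE 0.303, dim in controls), the tubulin Tubb2a (3.08, SE 0.147), the carbonyl reductase Cbr3 (3.02, SE 0.201), the annexin Anxa2 (2.96, SE 0.240) and Pdk4, an inhibitor of pyruvate dehydrogenase (2.78, SE 0.209). Mtmr11 (3.31), Ly6d (3.29, SE 0.481), D17H6S56E-5 (3.09), Ccdc120 (3.03) and Smoc2 (2.79) made up the 10. The largest falls were those of the methyltransferase Inmt (-3.64, SE 0.564), Hsd3b5 (-3.37), Upp2 (-3.07), Sult2a8 (-3.05), the ornithine aminotransferase Oat (-3.04, SE 0.145), Moxd1 (-2.74, SE 0.630), Serpina6 (-2.64), Mcm10 (-2.63), G6pc (-2.49) and Elovl3 (-2.49). The 4 values of a group lay beyond all 4 of the other for 3211 genes (25%, against 2.86% by chance). On the first principal component, with 60.7% of the variance, Rab5 replicate 1 stood at 17.5, apart from the other Rab5 arrays (30.3 to 38.3). Without the arrays numbered 2, which had the highest 3' to 5' difference of Gapdh in each group, 1545 genes were called, a choice made after seeing the data.

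Of the lists, 19 of 33 passed, 8 up and 11 down. With an estimated correlation 1 call held, that of the urea cycle and amino acid catabolism, and fry called 20 lists, 18 of them also called by camera.

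The lists of gluconeogenesis and of insulin and IGF signalling passed downwards. Of 16 gluconeogenesis genes 9 fell and 1 rose (11 and 1 adjusted over the list alone; list adjusted p = 2.17e-06, and adjusted p = 0.0884 with an estimated correlation). G6pc, which releases glucose from glucose 6-phosphate, went from 11.38 ± 0.337 to 8.89 ± 0.397 (SD, n = 4 each), a change of -2.49 (SE 0.194, adjusted p = 2.19e-06). Pck1 changed by -1.04 (SE 0.148), although another, dim probe set of it went the other way (0.56, adjusted p = 0.0169), and Fbp1 by -0.81 (SE 0.0986). Got1 (-1.62), Tat (-1.37) and the coactivator Ppargc1a (-1.06) fell too. Among 21 insulin and IGF signalling genes 5 fell and 2 rose (6 and 2 adjusted over the list alone; list adjusted p = 2.43e-03, and adjusted p = 0.107 with an estimated correlation). Insr, the insulin receptor, changed by -0.55 (SE 0.0992), Irs2 by -1.15 (SE 0.125), Igfbp3 by -1.27 and Igfals by -1.04. Foxo1 (-0.07), Irs1 (-0.09) and Igfbp2 (-0.07) did not pass. Igf1 (-0.25, adjusted p = 0.148) did not pass either, but did without Rab5 replicate 1 (-0.34, adjusted p = 0.0468). Igfbp1 rose by 0.69 (adjusted p = 0.0238), and its adjusted p was 0.0665 without control replicate 2, 0.0625 without control replicate 4 and 0.0695 without Rab5 replicate 4.

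Glycogen and glycolysis lists did not pass. Of 16 glycogen genes 2 rose and 4 fell (2 and 4 adjusted over the list alone; adjusted p = 0.951), among them the liver glycogen synthase Gys2 (-0.93, SE 0.109), Pygb (0.92, SE 0.175), Gyg (0.82) and the dim Ppp1r3g (-1.79, SE 0.443). For control siRNA minus PBS Ppp1r3g stood at 1.77 (SE 0.542, adjusted p = 0.949), so a fall of this gene against PBS is not shown. The median of the glycogen list was 0.10, while its mean (-0.04) and its test pointed down. Of 16 glycolysis and glucose uptake genes 5 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.430), with Aldoa at 0.56 and Pkm at 0.57. Pklr, the liver pyruvate kinase, fell by 0.70 (adjusted p = 0.0218). Its adjusted p was 0.0647 without control replicate 3, 0.0625 without control replicate 4, 0.0608 without Rab5 replicate 2, 0.055 without Rab5 replicate 3 and 0.0649 without Rab5 replicate 4.

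Lipid genes went in different directions by pathway. Cholesterol synthesis rose, with 15 of 20 genes up and 0 down (15 and 1 adjusted over the list alone; list adjusted p = 5.01e-09, and adjusted p = 0.156 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, rose by 1.93 (SE 0.210), Sqle by 1.43 (SE 0.145), Msmo1 by 1.43 and Mvd by 1.38. Fatty acid and triglyceride synthesis fell, with 10 of 21 down and 0 up (10 and 0 adjusted over the list alone; list adjusted p = 1.42e-04, and adjusted p = 0.240 with an estimated correlation). Thrsp changed by -1.96, Acacb by -1.20 and the carbohydrate-responsive factor Mlxipl by -0.88, whereas Fasn (-0.08) and Srebf1 (-0.25) did not pass. Of 23 genes of fatty acid oxidation and PPARalpha targets 11 fell and 2 rose (11 and 2 adjusted over the list alone; list adjusted p = 1.49e-03, adjusted p = 0.467 with an estimated correlation, and 0.0886 by fry). Ppara changed by -0.98 and Acaa1b by -1.56, while Acot2 (1.57) and Pdk4 (2.78) rose. The 19 genes of lipid droplets and lipid uptake did not pass as a list, with 3 up and 5 down (3 and 6 adjusted over the list alone; adjusted p = 0.498), among them Lpl (1.67), Fitm1 (-1.44) and Fitm2 (-0.97).

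Bile acid, amino acid and drug metabolism fell. Of 21 bile acid genes 12 fell and 3 rose (15 and 4 adjusted over the list alone; list adjusted p = 1.37e-04, and adjusted p = 0.0884 with an estimated correlation), among them the uptake transporters Slc10a1 (-1.57, SE 0.137) and Slco1b2 (-1.48), Cyp7b1 (-1.44) and Slc27a5 (-1.12). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, changed by -1.02 (SE 0.348) just under the threshold. Its adjusted p was 0.106, 0.123 and 0.113 without control replicates 1, 2 and 4, and 0.0592, 0.143 and 0.119 without Rab5 replicates 2, 3 and 4. In the urea cycle and amino acid catabolism 17 of 22 fell and 1 rose (17 and 1 adjusted over the list alone; list adjusted p = 1.39e-11, and adjusted p = 0.0311 with an estimated correlation), with Hal (-1.89), Prodh (-1.89), Mat1a (-1.74) and Hpd (-1.50). Of 19 drug-metabolising cytochromes P450 10 fell and 2 rose (10 and 2 adjusted over the list alone; list adjusted p = 1.45e-04, and adjusted p = 0.184 with an estimated correlation), with Cyp2c37 (-2.16), Cyp2c54 (-1.97), Cyp2c50 (-1.24) and Cyp3a25 (-1.20).

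Lists of hepatocyte identity did not pass, while male-biased genes fell. Of 25 secreted hepatocyte proteins 1 rose and 4 fell (1 and 3 adjusted over the list alone; adjusted p = 0.0755, but 0.0477 with array weights, 0.0478 without the arrays numbered 1 of both siRNA groups and 0.0095 by fry), with Ahsg at 0.69 and F7 at -0.45, while Alb was 0.05 (SE 0.0820). Of 14 hepatocyte transcription factors 2 rose and 3 fell (2 and 5 adjusted over the list alone; adjusted p = 0.305), with Cebpa at -0.88 and Foxa3 at 0.54. Male-biased liver genes fell, 11 of 15 down and 0 up (13 and 0 adjusted over the list alone; list adjusted p = 5.01e-09, and adjusted p = 0.0926 with an estimated correlation), among them Hsd3b5, Elovl3 and Nudt7 (-1.79). Female-biased genes did not pass, with 2 of 8 up and 1 down (2 and 2 adjusted over the list alone; adjusted p = 0.861), among them Atp6v0d2 (1.11) and Cyp17a1 (-0.66). Their median was -0.03, while the mean (0.08) and the test pointed up. Of 10 growth hormone and STAT5 targets 2 fell and 0 rose (2 and 0 adjusted over the list alone; list adjusted p = 0.0185, and adjusted p = 0.252 with an estimated correlation), the receptor Ghr (-0.85) and Igfals. Without Rab5 replicate 4 the adjusted p of this list was 0.0579.

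**Figure D2:**
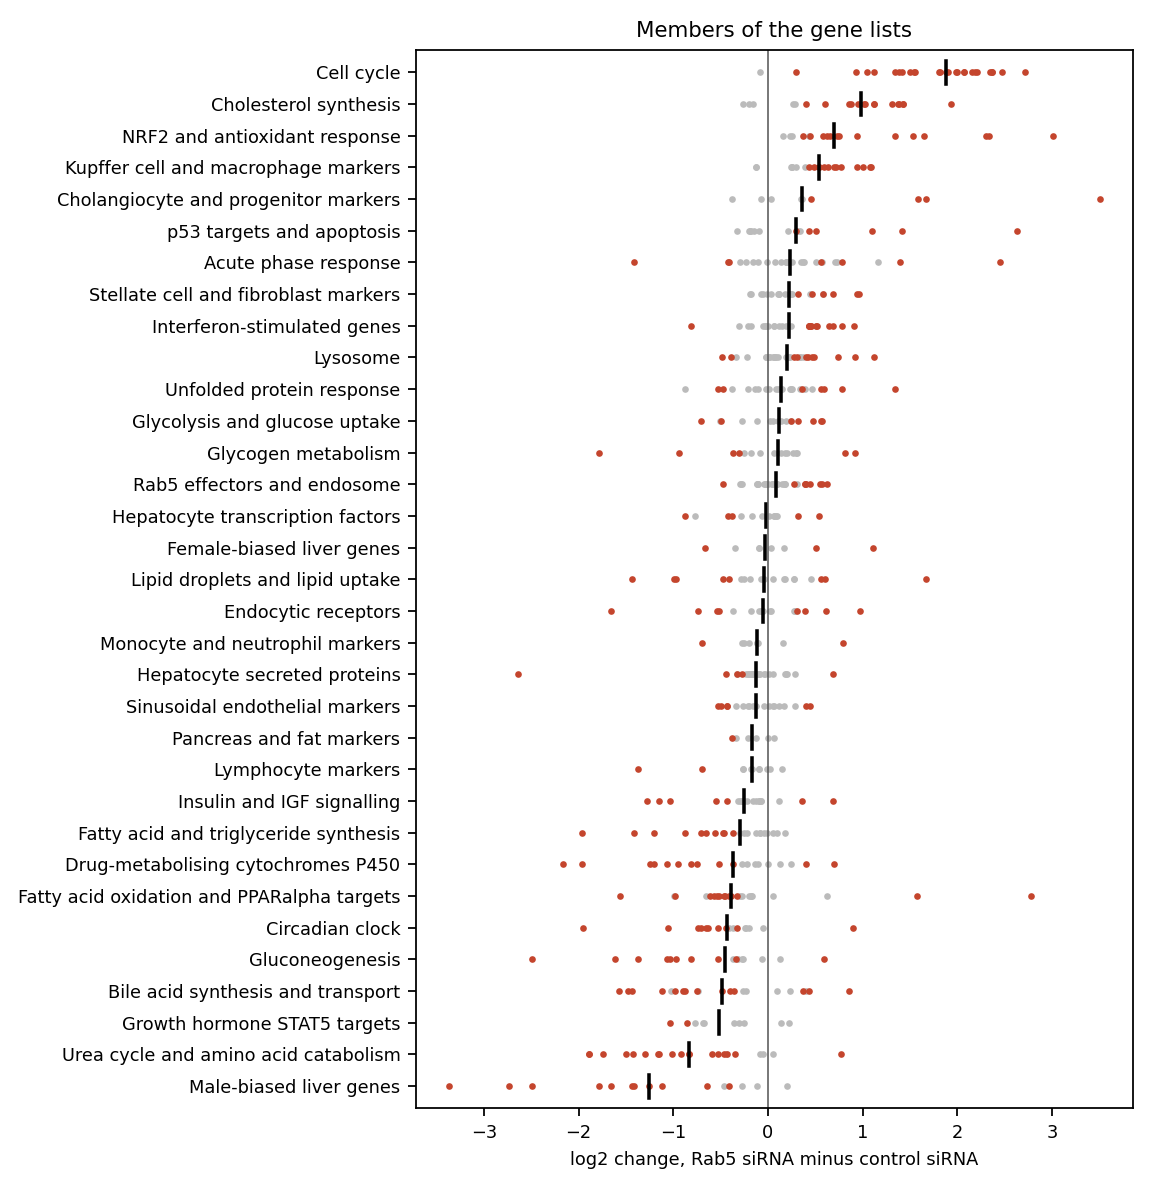
Log2 changes, Rab5 siRNA minus control siRNA, (horizontal axis) of the members of each tested gene list, each point being a gene, red if it passed and grey if not, with a black bar at the list median. Cell cycle genes lie highest (median 1.88), and male-biased genes (median -1.25) and genes of the urea cycle and amino acid catabolism (median -0.83) lie lowest.

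The cell cycle and NRF2 lists rose. Of 27 cell cycle genes 26 rose and 0 fell (26 and 0 adjusted over the list alone; list adjusted p = 1.27e-23, and adjusted p = 0.0822 with an estimated correlation), with Birc5 at 2.72 (SE 0.280), Ccnb2 at 2.47, Mki67 at 2.37 (SE 0.243) and Cdc20 at 2.37. The member that did not pass was at -0.09, and Mcm10, outside the list, fell. Kupffer cell scores of the same Rab5 arrays were 0.15, 0.67, 0.65 and 0.68 above the control mean. NRF2 and antioxidant genes rose, 14 of 18 up and 0 down (14 and 0 adjusted over the list alone; list adjusted p = 1.11e-09, and adjusted p = 0.0926 with an estimated correlation), with Srxn1 (2.34), Gstm3 (2.30) and Nqo1 (1.65). Of 15 p53 targets and apoptosis genes 6 rose and 0 fell (6 and 0 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 2.63 (SE 0.150), Btg2 at 1.41 and Phlda3 at 1.10. For control siRNA minus PBS Cdkn1a stood at -1.05 (SE 0.184, adjusted p = 0.149), so its rise over PBS was smaller. The list itself did not pass (adjusted p = 0.0697), but did without Rab5 replicate 1 (adjusted p = 0.0337), without the arrays numbered 1 of both siRNA groups (0.0382), with no filter (0.00418), with array weights (0.0477) and by fry (0.000718). Of 24 unfolded protein response genes 5 rose and 2 fell (8 and 3 adjusted over the list alone; adjusted p = 0.182), with Atf3 at 1.34 and Pdia3 at 0.78.

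Among inflammatory and clock genes, 11 of 26 interferon-stimulated genes rose and 1 fell (12 and 1 adjusted over the list alone; list adjusted p = 8.33e-03, and adjusted p = 0.460 with an estimated correlation), with Zbp1 (0.91), Oas1a (0.78), Ddx58 (0.69) and, down, Cxcl9 (-0.81). With the filter at the 75th percentile this call ended (adjusted p = 0.0623). Of 26 acute phase genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.430), with Mt2 at 1.4 and Saa4 at -1.42. Circadian clock genes fell, 9 of 16 down and 1 up (11 and 1 adjusted over the list alone; list adjusted p = 2.27e-04, and adjusted p = 0.0629 with an estimated correlation), with Dbp at -1.95, Tef at -1.05 and Arntl at 0.90. The hour at which the livers were taken was not among the sample details used here, so its part in these changes was not tested.

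The lists of endosomal genes and receptors did not pass, and that of lysosomal genes rose. Of 33 Rab5 effector and endosome genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.279), with Stx7 at 0.58, Rab4a at 0.55 and Mon1a at -0.47, while the tether Eea1 (0.17) did not pass. Of 18 endocytic receptors and adaptors 4 rose and 4 fell (5 and 5 adjusted over the list alone; adjusted p = 0.430), with Egfr at -1.66, Pigr at -0.74 and Tfrc at 0.97. Lysosome genes rose, 9 of 30 up and 2 down (11 and 3 adjusted over the list alone; list adjusted p = 0.0254, and adjusted p = 0.467 with an estimated correlation), with Lgmn (1.12), Gla (0.92), Asah1 (0.74) and Naglu (0.49), whereas Lamp1 (-0.02) did not pass. Lysosome scores of the 4 Rab5 arrays were 0.10, 0.18, 0.29 and 0.23 above the control mean, and their Kupffer scores 0.15, 0.67, 0.65 and 0.68. The adjusted p of this list was 0.0529 without control replicate 1, 0.0529 without control replicate 4 and 0.0551 without Rab5 replicate 3, and the filter at the 75th percentile (0.134), the mean of probe sets (0.0671) and the most variable probe set (0.291) ended the call too.

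Of the markers of other cell types, 4 lists passed. Kupffer cell and macrophage markers rose, 13 of 20 up and 0 down (16 and 0 adjusted over the list alone; list adjusted p = 2.65e-06, and adjusted p = 0.303 with an estimated correlation), with Cd68 at 1.08 (SE 0.113), Cd5l at 1.01 (SE 0.122) and Mpeg1 at 0.94 (SE 0.179). The list of cholangiocyte and progenitor markers rose, 4 of 9 up and 0 down (5 and 0 adjusted over the list alone; list adjusted p = 4.67e-03, and adjusted p = 0.0884 with an estimated correlation), with Afp and the keratins Krt18 (1.67) and Krt8 (1.59). Its mean (0.83) lay above its median (0.36), so these members weighed heavily, and which cells expressed them was not tested. Stellate cell and fibroblast markers rose, 6 of 21 up and 0 down (6 and 0 adjusted over the list alone; list adjusted p = 0.0265, and adjusted p = 0.508 with an estimated correlation), with Vim (0.96), Col4a1 (0.94) and Acta2 (0.69). Lymphocyte markers fell, 2 of 11 down and 0 up (2 and 0 adjusted over the list alone; list adjusted p = 0.0472, and adjusted p = 0.240 with an estimated correlation), Ighm by 1.38 on the log2 scale. The stellate list had adjusted p = 0.0788 and 0.0594 without control replicates 1 and 3, and 0.0528 and 0.0507 without Rab5 replicates 3 and 4. The lymphocyte list had adjusted p = 0.0529, 0.0579 and 0.0746 without control replicates 1, 2 and 4, and 0.0505, 0.0787 and 0.0625 without Rab5 replicates 1, 3 and 4. Several other settings ended these calls too, among them the mean of probe sets (0.0519 for stellate and 0.0602 for lymphocyte markers), the filter at the 75th percentile (0.190 for stellate markers) and quantile normalization (0.109 for lymphocyte markers). Sinusoidal endothelial markers did not pass, with 2 of 19 up and 4 down (2 and 4 adjusted over the list alone; adjusted p = 0.223), among them Ptprb (-0.53), Gpr182 (-0.50) and Clec4g (-0.43). Monocyte and neutrophil markers did not pass, with 1 of 9 up and 1 down (1 and 1 adjusted over the list alone; adjusted p = 0.325), Plac8 being at 0.79. Pancreas and fat markers did not pass, with 1 of 6 down (1 adjusted over the list alone; adjusted p = 0.169), Prss2 at -0.38. Of 4 red blood cell markers, too few to test as a list, 1 rose and 1 fell (1 and 1 adjusted over the list alone), Alas2 by 1.67 on the log2 scale.

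**Figure D3:**
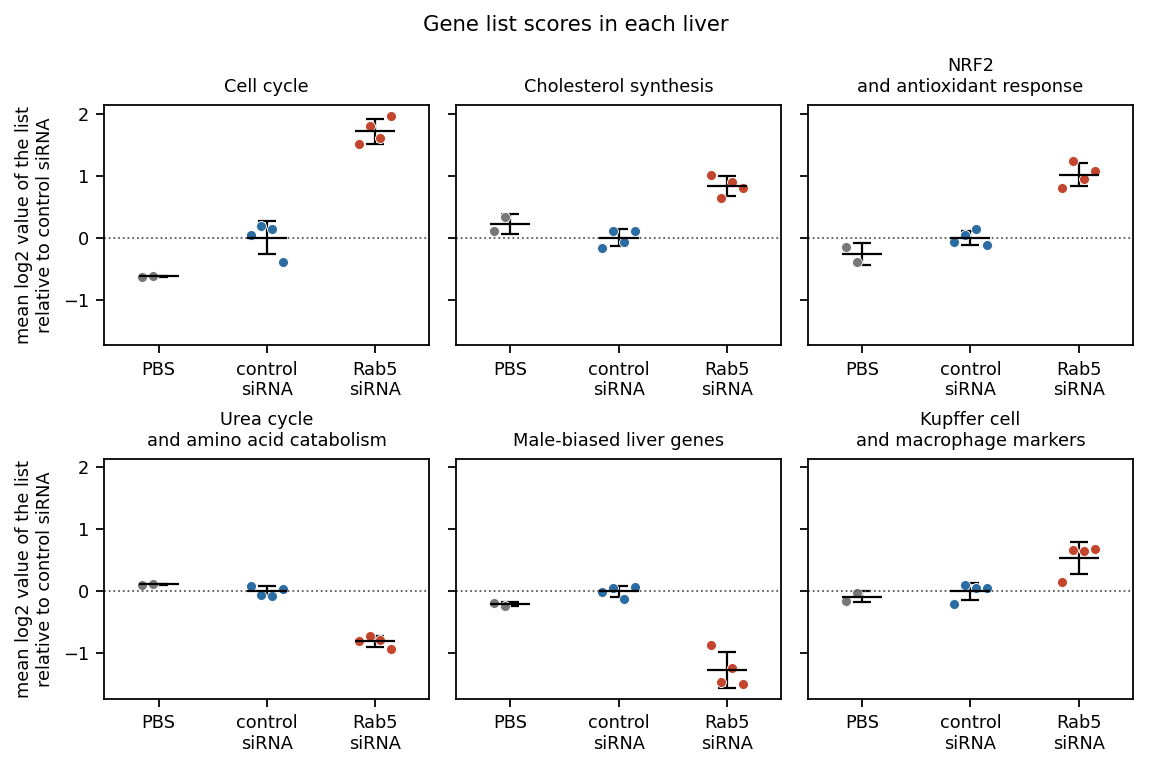
Mean log2 value of the members of 6 gene lists in each array (points), set to 0 at the mean of the control siRNA arrays (vertical axis, dotted line at 0), by group, with lines for the group mean and SD. The cell cycle scores of the Rab5 siRNA arrays lie between 1.51 and 1.96, and their Kupffer scores between 0.15 (replicate 1) and 0.68.

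Of 2 measures used for RNA quality, that of Actb differed between the groups and that of Gapdh did not. The 3' minus 5' difference of the Gapdh control probe sets was 2.41 ± 0.178 with Rab5 siRNA and 2.41 ± 0.308 with control siRNA (SD, n = 4 each; exact permutation p = 1, 2-sided). That of Actb was 2.68 ± 0.0658 and 2.96 ± 0.185 (SD, n = 4 each; exact permutation p = 0.0286, the smallest that 4 against 4 allows, with the replicate pairs ignored). The Actb probe sets themselves were higher with Rab5 siRNA, the 3' one by 0.688, the middle one by 0.93 and the 5' one by 0.97 (exact permutation p = 0.0286 for each, n = 4). The Actb difference may therefore reflect the level of Actb or RNA quality, and these cannot be told apart here.

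The control siRNA against PBS shows what the particles with a control siRNA do. limma called 0 of 12855 genes, with 554 at an unadjusted p under 0.05 against 643 by chance and a smallest adjusted p of 0.0808. That was Gstm3, a glutathione transferase, at 1.58 (SE 0.218). On simulated data of this comparison 93.5% of changes of 1 and 0.5% of changes of 0.5 were called. Of the lists, 10 passed, 6 up and 4 down, but 0 with an estimated correlation and 0 by fry. Cell cycle genes rose by a median of 0.59 (adjusted p = 4.15e-23, and adjusted p = 0.261 with an estimated correlation), with 26 of 27 above PBS and 13 called when adjusted over the list alone, against 0 over all genes. Their scores were -0.63 and -0.61 with PBS and 0.05, 0.19, 0.15 and -0.38 with control siRNA. This was the only list call that held without each single array. Without control replicate 4 limma called 18 genes, 9 of them in the cell cycle list (Cdc20 at 2.15 and Ccnb2 at 2.11, chosen after their values were seen). Without control replicate 1 it called 4 (Gstm3, Elovl6 and Cib3 up, Cdkn1a down). Without Rab5 replicate 2 it called 2 (Gstm3 and Cib3), and without Rab5 replicate 1 it called 1 (Gstm3). These names were also chosen after their values were seen. With the replicate number as a block, Gstm3 was called (1.63, adjusted p = 0.0111).

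The other 9 list calls for control siRNA against PBS each ended when a single array was left out. In each of these 9 limma called 0 members over all genes. Upwards passed NRF2 genes (median 0.15, 3 called adjusted over the list alone; adjusted p = 1.07e-04, and adjusted p = 0.589 with an estimated correlation), fatty acid and triglyceride synthesis (0.15, 1 called adjusted over the list alone; 9.99e-04, and 0.589), male-biased genes (0.14; 0.0149, and 0.589), endothelial markers (0.10; 0.0464, and 0.595) and monocyte and neutrophil markers (0.21; 0.0464, and 0.589). Downwards passed acute phase genes (median -0.28; 2.51e-08, and 0.589), cholesterol synthesis (-0.20; 1.92e-04, and 0.589), each with 1 member called adjusted over the list alone, Rab5 effectors (-0.09; 0.0394, and 0.589) and fatty acid oxidation (-0.10; 0.0394, and 0.665). In the other 5 lists 0 members were called adjusted over the list alone. Acute phase scores were -0.05 and 1.03 in the PBS livers. Without PBS replicate 2 the adjusted p was 0.557 for acute phase genes, whose median became 0.02, and 0.114 for NRF2, 0.175 for fatty acid synthesis, 0.216 for cholesterol synthesis, 0.150 for male-biased genes and 0.0542 for monocyte markers. Without PBS replicate 1 it was 0.180 for fatty acid oxidation, whose median became 0.17, 0.428 for Rab5 effectors, 0.595 for endothelial and 0.380 for monocyte markers, and 6 lists passed. Without control replicates, the adjusted p was 0.126 (replicate 1) and 0.0851 (replicate 2) for Rab5 effectors, 0.0983 (3) and 0.331 (4) for fatty acid oxidation, 0.0558 (4) for male-biased genes, 0.314 (2) and 0.0983 (3) for monocyte markers, and 0.146 (3) and 0.102 (4) for endothelial markers. Without Rab5 replicate 4 it was 0.0508 for both monocyte and endothelial markers. With the replicate block, fatty acid oxidation (-0.08, adjusted p = 0.387) and monocyte markers (0.12, 0.170) no longer passed, while circadian clock genes (0.25, 0.00957) and lipid droplet genes (0.12, 0.0404) did.

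For Rab5 siRNA against PBS, the other control, limma called 2201 genes, 1225 up and 976 down, of which 554 changed at least 2-fold. Rab5a changed by -1.88 (SE 0.215), Rab5c by -2.07 (SE 0.134), G6pc by -2.08 (SE 0.237), Hmgcs1 by 1.29 (SE 0.257), Afp by 3.40 (SE 0.371) and Cdc20 by 4.19 (SE 0.318). Cell cycle genes rose (26 of 27; median 2.29), as did NRF2 (14 of 18) and cholesterol synthesis genes (12 of 20), and genes of the urea cycle and amino acid catabolism fell (15 of 22; median -0.99, list adjusted p = 5.01e-13, and adjusted p = 0.0219 with an estimated correlation). Adjusted over the list alone the counts were 26, 16, 13 and 18. The adjusted p with an estimated correlation was 0.0589 for cell cycle, 0.0818 for NRF2 and 0.287 for cholesterol synthesis. Of the 19 lists called against the control siRNA 16 passed here too, 1 of them with an estimated correlation and 14 by fry. Those that did not were fatty acid and triglyceride synthesis (median -0.12, against -0.29 for the control siRNA; adjusted p = 0.0640), growth hormone and STAT5 targets (-0.10, against -0.52; 0.103) and lymphocyte markers (-0.18, against -0.17; 0.103, and 0.0298 by fry). Circadian clock genes fell with 4 of 16 down and 0 up (4 and 0 adjusted over the list alone; list adjusted p = 0.0349, and adjusted p = 0.177 with an estimated correlation), and male-biased genes with 7 of 15 down and 0 up (11 and 1 adjusted over the list alone; 3.13e-06, and 0.180). Both falls were smaller here, with medians of -0.20 (against -0.43 for the control siRNA) and -0.57 (against -1.25). Of the genes called up, 1102 (90%) were also called up against the control siRNA, and of those called down 790 (80.9%), with 0 in opposite directions. Both comparisons share the Rab5 arrays, and independent lists would share 169 and 93. Simulated unchanged groups shared 0, but unchanged groups give few calls to share, so this does not show what the shared arrays add. With separate Rab5 arrays for each comparison, over 6 splits, 365 to 741 were shared up and 234 to 473 down. Without PBS replicate 1 the count was 1116, without PBS replicate 2 it was 1292, and without the arrays numbered 2 it was 799.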

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

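Apart from the count of splits, the tests here were chosen after the results were seen. The exact permutation p values ignore the replicate pairs, and within 4 pairs the smallest 2-sided p is 0.125. In 374 groups of 4 arrays, 25 values stood apart from the other arrays of their group by a gap above Dixon's critical value for 4 samples, against 19 by chance. Control replicate 1 held 8 of them. Its log2 values were 6.901 for Lpl (others 7.685 to 7.816), 10.52 for G0s2 (8.999 to 9.175), 12.86 for Hpd (12.6 to 12.63), 8.831 for Perp (9.384 to 9.483), 8.016 for Plac8 (8.39 to 8.434) and 8.399 for Srebf1 (9.001 to 9.111), with list scores of -0.2021 for Kupffer cell markers (0.0501 to 0.1003) and -0.0465 for cholangiocyte and progenitor markers (0.0134 to 0.0195). Control replicate 3 stood apart for Prodh (9.21), Fbp1 (12.98) and Cyp7a1 (7.644, others 8.651 to 8.834), and for the scores of glycogen (0.0993) and lymphocyte markers (-0.0786). Control replicate 4 was low for Ccnb2 (4.055, others 5.442 to 5.691), Mki67 (4.516, others 5.477 to 5.584) and the circadian clock score (-0.1239), and control replicate 2 was high for Ngp (6.437, others 5.09 to 5.266). Rab5 replicate 1 stood apart for Gys2 (7.577), Slc10a1 (9.793, others 9.274 to 9.32), the p53 score (0.232, others 0.4487 to 0.4889) and the Kupffer score (0.1503, others 0.6528 to 0.6801). The others were Sqle (9.123) and Cyp3a25 (10.89) in Rab5 replicate 2, Car2 (5.947) in Rab5 replicate 3 and Igfbp1 (12.19) in Rab5 replicate 4.

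Probe sets with no single gene name, outside the comparisons by gene, changed too: 538 of 3213 passed for Rab5 siRNA against control siRNA, 263 up and 275 down (16.7%, against 21.8% of those with 1 name).

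The 2993 genes called for Rab5 siRNA against control siRNA were weighed against chance and RNA quality. The real split was 1 of 35 splits of the 8 arrays to give as many, a share of 0.0286, and the highest of the others gave 0. This share holds for splits that ignore the replicate pairs. The 8 splits that part all 4 pairs are too few for a share under 0.05 (2993 for the real one, 0 for the highest other). With the pairs kept, chance is therefore not excluded by this count. With the Gapdh 3' minus 5' difference as a covariate, 2922 of the genes stayed called in the same direction, but its group means lay 0.0055 apart, so the covariate could not have removed a group difference and this decides nothing. The Actb difference lay lower by -0.282 in the Rab5 arrays with no overlap, and the Actb probe sets rose unequally, so degradation and a change of Actb itself cannot be told apart.

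The rise of Kupffer cell markers may reflect more or altered macrophages, or a lower share of hepatocytes. The list median was at least 0.4962 under both other scalings, but the medians of the deposited values per array lay only between 4.29 and 4.37. Other scalings could therefore move the list median little, and this decides nothing about array scaling. A lower hepatocyte share would raise the markers of all other cell types alike. The change of the Kupffer score exceeded that of the endothelial score by 0.626 (exact permutation p = 0.0571), and that of the mean of the endothelial, monocyte and stellate scores by 0.506 (exact permutation p = 0.0286), beyond a bound of 2 SD under 2 of 4 choices of lists. The scores of 6 cell types diverged with the groups, as did those of the 4 above the upper quartile (exact permutation p = 0.0286 each). Over the 6 types the highest change (0.835) was that of cholangiocyte and progenitor markers. Which cells expressed these was not tested, so the divergence of the 6 types does not decide on the hepatocyte share. With single markers near the floor left out, or without monocytes, the p was 0.0571 and 0 pairs of types lay 2 SD apart. The score of secreted hepatocyte proteins differed by -0.169 (exact permutation p = 0.0286), with 1 of 25 members called up and 4 down. A lower share therefore stays open, as do the number and state of macrophages.

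The rise of cell cycle genes could come from hepatocytes or from other dividing cells. The lymphocyte score changed by -0.27 (exact permutation p = 0.0286), but 10 of its 11 markers lay under the upper quartile of all values (6.08), too near the floor to exclude a small dividing population. The monocyte and neutrophil score differed by -0.0895 (exact permutation p = 0.629), which decides nothing. The Kupffer score rose by 0.538 (exact permutation p = 0.0286), so dividing Kupffer cells stay open, although Rab5 replicate 1 had a Kupffer score of 0.15 with a cell cycle score of 1.51. Division of hepatocytes, the biological explanation, was not tested.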

How the results depend on the processing

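The removal of the arrays numbered 1 or 2 and the Gapdh covariate were chosen after seeing the data. For Rab5 siRNA against control siRNA, leaving out 1 array gave 2214 (without Rab5 replicate 2) to 3426 genes (without Rab5 replicate 1), and the replicate block gave 3712, with 2981 of the 2993 among them. Stricter thresholds gave 1730 (adjusted p under 0.01) and 496 (at least 2-fold), as they must. The share of called genes that rose was 59.2%, and 51.6% with quantile normalization and 64.1% with median centring. Without the arrays numbered 2 the count was 1545, with 1529 of the 2993 still called, in a fit with fewer arrays. For control siRNA against PBS, where 0 genes were called, quantile normalization gave 2 (Gstm3 and Elovl6), array weights 3 (these and Cdca5), the replicate block 1 and the Gapdh covariate 1 (Gstm3), the removal of the arrays numbered 1 of both siRNA groups 5 (Gstm3, Cdkn1a, Elovl6, Gadd45g and Cib3), and leaving out 1 array 0 to 18. Of the genes named here, Cdkn1a and Gadd45g were lower with control siRNA and the others higher. They were all named after their values were seen, and the cause was not tested. For Rab5 siRNA against PBS, leaving out 1 array gave 1116 to 2633, the thresholds 1232 and 554, and removal of the arrays numbered 2 gave 799. Rab5a and Rab5c stayed called in the same direction under every alternative run (leaving out 1 array, -1.92 to -1.61 and -2.05 to -1.92), and Rab5b stayed uncalled (-0.34 to -0.16), except that the filter at the 75th percentile removed it. The number of lists called for Rab5 siRNA against control siRNA was 19, and 1 with an estimated correlation and 16 to 19 without 1 array, newly called lists included. For control siRNA against PBS it was 10, and 3 without the arrays numbered 2, 6 with the Gapdh covariate, 0 with an estimated correlation, 0 by fry, and 6 to 14 without 1 array. Lists not called there gained a call, Kupffer cell markers (adjusted p = 0.0509) in 13 of 25 settings (0.00146 without control replicate 1), circadian clock genes in 10, urea cycle genes in 8, stellate markers in 7, and interferon-stimulated and lipid droplet genes in 1 each. There, acute phase genes turned up without PBS replicate 2 (medians over left-out arrays -0.74 to 0.0221) and without the arrays numbered 2 (0.0710), and fatty acid oxidation turned up without PBS replicate 1 (medians -0.34 to 0.17), for causes not tested. Of 139 named genes called, 102 kept the call under every alternative that tested them, 20 changed it without 1 array, 32 lost it without the arrays numbered 2, and 0 reversed. Of 10 named genes not called, Rab5b apart, 3 gained a call under at least 1 alternative. Apart from the values given with the results, the replicate block changed no list call. Signal over background limits dim genes, whose changes are compressed.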

Other observations

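Gene families formed from symbol stems with at least 8 measured members were tested with camera after the data were seen, as a description and not as lists fixed in advance. Of 205 families, 11 passed for Rab5 siRNA against control siRNA, and 0 with an estimated correlation. Annexins rose, 5 of 8 up and 0 down (adjusted p = 6.63e-04, and adjusted p = 0.822 with an estimated correlation), with Anxa5 at 1.99 and Anxa4 at 0.86. The Mcm family, of which several members unwind DNA at replication, had 6 of 9 up and 1 down (0.0148, and 0.822), with Mcm5 at 2.35 and Mcm10 at -2.63. Ribosomal protein genes rose in both stems, Rpl with 10 of 22 up and 0 down (0.00169, and 0.894; Rpl22l1 at 1.37 and Rpl12 at 0.69) and Rps, which also holds ribosomal S6 kinases, with 10 of 26 up and 0 down (0.0148, and 0.822). Ifi genes had 5 of 11 up (0.0148, and 0.822) and Nup genes 6 of 19 (0.0313, and 0.971).

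Families that fell were cytochromes P450, 26 of 58 down and 7 up (adjusted p = 6.63e-04, and adjusted p = 0.857 with an estimated correlation), Aldh, 7 of 17 down and 1 up (0.0286, and 0.822; Aldh18a1 at 1.91 and Aldh1l1 at -0.84), carboxylesterases, 6 of 12 down and 2 up (0.0396, and 0.971; Ces1e at -1.84 and Ces2a at -1.74), Atg, 5 of 18 down (0.0215, and 0.822), and Pex, 3 of 14 down (0.0148, and 0.857). The directions of all 11 were the same under both other scalings, and Nup and Ces no longer passed with quantile normalization. All genes of these families were chosen after their values were seen. The Cyp and Mcm stems overlap the lists of drug metabolism and cell cycle.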
